A study of Ruditapes philippinarum with 32 samples.

How the data were processed

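Hemocytes, the circulating immune cells of the Manila clam Ruditapes philippinarum, were cultured with its protozoan parasite Perkinsus olseni and their RNA was hybridised to one-colour Agilent arrays. The challenges were trophozoites (the proliferating stage, T), zoospores (the swimming stage, Z) and medium holding extracellular products (ECP). The sample descriptions attribute these products to the parasite, while the treatment protocol once calls them products of hemocytes, so their origin is not settled and ECP stands for either. Per the labels' protocols, a membrane insert with pores of 0.2 µm kept parasites and hemocytes apart in the wells, and Cy3-labelled cRNA was made from 50 ng of RNA collected at 1, 8 and 24 h. The series design states that each of 3 biological replicates was a pool of hemocytes from 10 clams. It also states that control replicates were pooled before hybridisation, so a control is 1 array per challenge and time, and for zoospores 1 array over all times. The description of the zoospore control names 1 h alone, against the design and its own title. It was used as the control for all times, and if it holds 1 h alone, the 8 and 24 h differences from it and their mean mix challenge with time. The 32 samples fall into 16 groups: ECP and T have 3 challenged arrays per time point, and zoospores have 3, 2 and 2 at 1, 8 and 24 h.

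The scanner files hold spot intensities on a linear scale that the authors deposited without normalization between arrays, per the file headers. They were made with Agilent Feature Extraction 9.5, per the submitters' processing notes. The authors also deposited a table of normalized intensities, whose columns share a median of 238 and list a probe only where the scanner marked it as well above background. How that table was normalized is not given in the sources used here. Its equal medians and maxima are those of quantile normalization over the probes present in each column, and its values are on a linear scale without centring. The files do not pair probes with gene names, and 0 probe names matched the reference table of clam genes, so probes are named by their identifiers, with the printed sequence as identity. Their genome positions are not known, and the tests of gene lists were not run.

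The scanner file listed for the T control at 24 h was identical, byte for byte, to that of the ECP control at 24 h, and its slide position was that of the ECP control. It was left out, leaving 31 arrays in 15 groups. This departs from the planned design: the mean T effect covers 1 and 8 h, as do the differences that involve T and the comparison of T with ECP controls. The change of the T effect with time is 8 h minus 1 h. For T at 24 h the deposited table was used, with the columns quantile normalized again over the 5481 sequences that are present in every column and pass the filter, a choice made after the data were seen. As deposited, the T control column at 24 h lists 49.3% of probes. Its log2 median over the complete probes is 8.28, against 9.13 to 10.49 in the other columns, so levels as deposited cannot be compared between it and the other columns.

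Each array holds 15151 spots, 536 of them control spots, which were left out, as were spots with outlier flags. The 14615 clam probes hold 13764 distinct sequences from 11052 contigs, and spots of one sequence were averaged. Levels are log2 of the background-subtracted signal minus the 75th percentile of that array. The 12390 sequences well above background on at least 3 arrays were tested, and 1374 were not. A probe below background on every array of a group has only a bound there. Its fold is then given as "at least", from the mean of the bright group against the mean over arrays of the higher of the lowest signal well above background and the probe's own. In a mean over ECP time points, this was applied at the time points where it holds.

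Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with each group given its own mean and one spread per probe pooled over the challenged groups (16 residual degrees of freedom, 2.92 prior). A lone control is assumed to vary like the challenged replicates. Every control array in the fit of scanner values lay in slide column 1, and no challenged ECP or T array did. Position and challenge therefore cannot be told apart in the ECP and T comparisons against control. Adjusted p-values follow Benjamini and Hochberg over probes within a comparison, with a threshold of 0.05. The mean effect of a challenge is the mean of its differences from control over time points. Changes of an effect with time were tested with a moderated F test for ECP. Overlaps of calls are set against the product of the list sizes over the probes tested in both. The mean comparisons share no arrays, and the zoospore time points share their control array, so no overlap among these is given. Spreads come from a common estimate per probe, which raises overlaps of either direction.

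Samples, groups, tests, the main alternatives and the rule for named probes were fixed before the data were examined. Without annotation, that rule names at most 2 probes that rose and 2 that fell per comparison, the largest changes past the threshold with the same sign at each time point. As the mean T effect gave none, the largest changes at 1 h were named for T, which was decided after the data were seen. The alternatives were normexp background correction (offset 50), quantile normalization, no filter, the deposited table, fits within a challenge, an additive model, the replicate number as a block, and leaving out each array. Averaging arrays that differed by an SD under 0.25 log2 (close arrays) was added after the data were seen, as was leaving out both zoospore arrays at 24 h. Per array, 60.8% to 87.5% of probes were well above background, and the number of arrays limits the precision.

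The fit was tested on simulated data with 200 changed probes among 12335. It found 25.0% of changes of 1 log2 unit and 79.0% of changes of 2 in the mean ECP comparison, 14.0% and 67.0% for T, and 5.0% and 46.0% for Z. For single time points it found at most 2.0% of changes of 1 unit, and 12.0% to 41.0% of changes of 2. In the mean comparisons, unchanged probes made up 0 of 104 calls for ECP, 8 of 89 for T and 2 of 53 for Z. The simulated arrays were independent, and controls had the same spread as challenged arrays. These rates therefore assume that close arrays are separate samples and that lone controls vary like challenged replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.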

Results

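The study asked how clam hemocytes respond to living stages of Perkinsus olseni and to extracellular products over 24 h in culture. Signal was measured on 31 arrays: 12 for ECP, 11 for T and 8 for zoospores, with 1 more T array, the control at 24 h, known from the deposited table. The 75th percentile of array signal ran from 112 to 1507, and the lowest values, 112 and 184, belonged to the zoospore arrays at 24 h. At most 3 spots per array were saturated.

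Replicate arrays of a group were not equally far apart. In 6 of 23 pairs the SD per array, from the scaled median absolute deviation of the differences in probe level, was 0.09 to 0.21 log2: all pairs among the zoospore arrays at 1 h, the pair at 8 h, T at 1 h replicates 2 and 3, and T at 24 h replicates 1 and 2. In the other 17 pairs it was 0.27 to 0.65, with a median of 0.37. By the same measure, spots of one sequence within an array had an SD of 0.05 to 0.16. The close pairs differed by 1.25 to 3.23 times the higher spot SD of their arrays, and the other pairs by 2.99 to 10.8 times. Spot noise leaves out labelling and hybridisation, so these ratios do not tell separate pools from repeat hybridisations of a pool, and no label states it for single arrays. All were kept as separate samples, as the labels number them. If the close arrays are repeats, the pooled spread is too small and the counts below too large, so counts with close arrays averaged are given as well.

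Extracellular products changed 294 of 12385 probes averaged over the time points, with 147 higher and 147 lower than in control arrays. The median size of these changes was 1.33 log2, and 229 were at least 2-fold. Probe comp373622_c0_seq3reverse.1 (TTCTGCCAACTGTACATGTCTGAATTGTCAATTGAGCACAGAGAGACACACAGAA) was at least 9.11-fold higher (measured difference 3.81 ± 0.51 log2, SE, 9 challenged and 3 control arrays, adjusted p = 0.00166), and Contig10510reverse.1 (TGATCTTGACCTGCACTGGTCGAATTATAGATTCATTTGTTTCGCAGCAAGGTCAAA) at least 5.56-fold higher (2.68 ± 0.50, adjusted p = 0.0103). Their controls at 8 h and at 24 h, in that order, were not well above background. Probe Rphi_rep_c43651reverse.0 (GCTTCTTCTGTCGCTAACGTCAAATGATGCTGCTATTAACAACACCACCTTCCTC) was at least 12.9-fold lower (-4.25 ± 0.80, adjusted p = 0.0109), as it was not well above background on any challenged array at 24 h, and Rphi_rep_c3791.1 (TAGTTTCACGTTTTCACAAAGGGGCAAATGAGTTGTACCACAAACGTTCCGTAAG) fell by 3.68 ± 0.51 (adjusted p = 0.00166), well above background on 4 of the 9 challenged arrays. Of the 147 probes that rose, 121 had a positive difference at every time point, and medians over all 147 were 0.76 at 1 h, 1.77 at 8 h and 1.17 at 24 h. Of those that fell, 127 had a negative difference at every time point, and medians over all 147 were -0.76, -1.75 and -1.49. Where the contig of a called probe carried a second probe, that partner had the same sign in 139 of 146 cases (95.2%).

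Leaving out a lone control also takes its time point out of the mean, so the effects of both on these calls cannot be separated. For comp373622_c0_seq3reverse.1 the control level was -8.55 log2 at 8 h, not well above background, against -3.04 and -4.40 at 1 and 24 h. Without the ECP control at 8 h its difference was 1.87 (adjusted p = 0.288) and that of Rphi_rep_c3791.1 was -2.65 (adjusted p = 0.0915). Without the ECP control at 24 h, Contig10510reverse.1 differed by 1.504 (adjusted p = 0.171) and Rphi_rep_c43651reverse.0 by -2.55 (adjusted p = 0.1504). The count of 294 became 28 without the ECP control at 8 h, 134 without that at 24 h and 778 without that at 1 h. With all time points kept, it was 168 and 464 without ECP at 1 h replicates 1 and 2, 147 without ECP at 8 h replicate 1 and 463 without ECP at 24 h replicate 1. It was 13 with close arrays averaged, when Contig10510reverse.1 and Rphi_rep_c43651reverse.0 no longer passed (adjusted p = 0.0853 and 0.0808). The additive model gave 0, with adjusted p-values of 0.148 to 0.184 for the named probes. The arrays of this challenge alone gave 34, comp373622_c0_seq3reverse.1 among them and the other named probes at adjusted p-values of 0.0537 to 0.0759. Under normexp the 4 differences shrank to 1.42 and 0.95 log2 for the rises, which no longer passed (adjusted p = 0.0654 and 0.124), and to -2.17 and -1.55 for the falls, which did (adjusted p = 0.00553 and 0.0113). The values of the 3 probes with a bound lie below it. Quantile normalization called 364 probes, 63.7% of them higher, against 50.0%, and with the deposited values 89 passed, 38.2% of them higher.

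**Figure D1:**
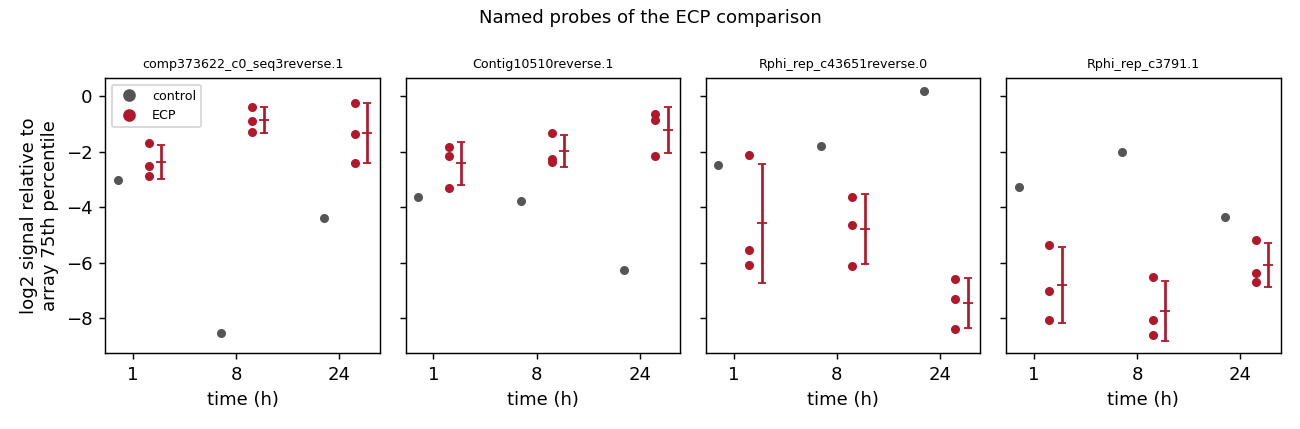
Level of each named ECP probe (log2 signal relative to the 75th percentile of its array, vertical axis) against time (h, horizontal axis). Grey points are control arrays, red points challenged arrays, and bars the mean and SD of 3 challenged arrays; the control of comp373622_c0_seq3reverse.1 lies at -8.55 at 8 h, far below its levels at 1 h (-3.04) and 24 h (-4.40).

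By time point, ECP changed 7 probes at 1 h (2 rose and 5 fell), 1028 at 8 h (545 rose and 483 fell) and 172 at 24 h (100 rose and 72 fell). At 8 h, probes of the Rphi_rep_c contigs, with a median level of 2.31 log2, rose in 284 cases and fell in 59. Under quantile normalization these were 159 and 99, and under normexp 174 and 40. Probes of the comp contigs, with a median level of -3.13, rose in 87 cases and fell in 205, but 127 rose and 125 fell under quantile normalization. Of the probes called at 8 h, 12 rose and 9 fell at 24 h as well, where independent lists would share 4.40 and 2.81, and with close arrays averaged no called probe was shared. A test of whether the ECP effect changed with time found 63 probes, and 7 with close arrays averaged. That count was 36 and 12 without the controls at 8 and 24 h, which drops these time points, and 96 without ECP at 24 h replicate 1. With close arrays averaged, 0, 28 and 39 probes passed in limma at 1, 8 and 24 h. At 1 h, 661 of 12388 probes had an unadjusted p under 0.05 with each array counted. The 8 h count was 234 without replicate 1, 354 without replicate 3 and 5 from the arrays of this challenge alone, and the 1 h count was 2 without replicate 1. At 24 h normexp called 40 probes, 16 higher and 24 lower, against a share of 58.1% higher, and at 8 h the deposited table called 207, 19.3% of them higher, against 53.0%.

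**Figure D2:**
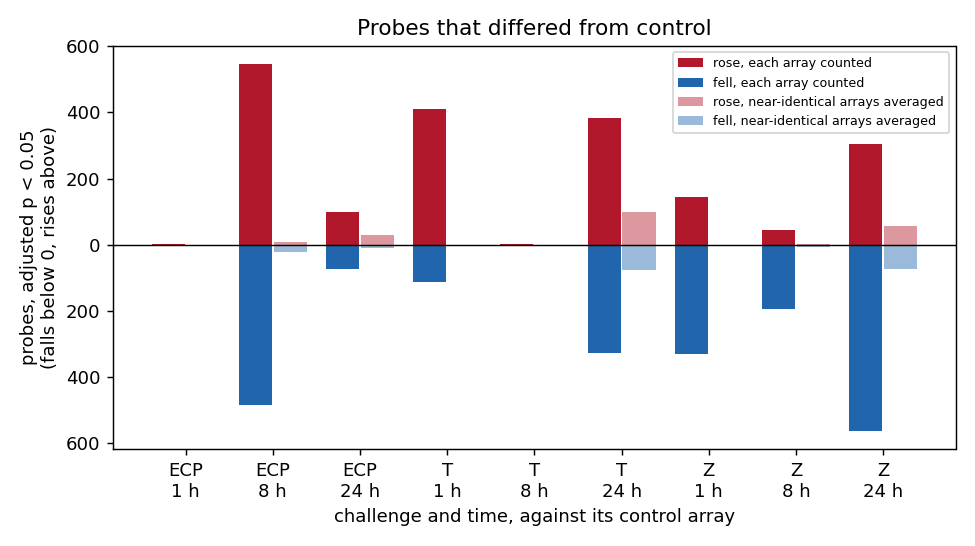
Number of probes past the threshold (vertical axis, rises above 0 and falls below) for each challenge and time against its control (horizontal axis). Bars of T at 24 h come from the deposited table normalized again over 5481 complete probes, and all others from scanner values over more probes. Dark bars count each array and pale bars average the close arrays; the tallest dark bar for rises is ECP at 8 h (545), where the pale bars stand at 7 rises and 21 falls.

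Trophozoites changed no probe in limma averaged over 1 and 8 h: 0 of 12380 passed, the smallest adjusted p was 0.0541, and 1503 had an unadjusted p under 0.05. The additive model called 1 probe, and 0 passed in limma with close arrays averaged. The count was 524 without the T control at 8 h, which leaves 1 h alone, 96 without T at 8 h replicate 2, 8 without T at 1 h replicate 1 and 4 without the T control at 1 h, which leaves 8 h alone. Quantile normalization called 5, and the deposited table ranked again over complete probes, which adds 24 h to the mean, 384.

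At 1 h, trophozoites changed 524 of 12388 probes, of which 411 rose and 113 fell, with a median size of 1.89 log2. Probe Rphi_rep_c28401.0 was at least 1596-fold higher than in the control, where it was not well above background (log2 level 5.21 ± 2.26, SD, n = 3, limma adjusted p = 0.0232). Its sequence ends with the opening bases of a primer in wide use for cDNA amplification (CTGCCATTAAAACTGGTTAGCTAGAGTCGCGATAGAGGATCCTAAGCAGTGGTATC), so it is not settled that this value measures a clam transcript. Rphi_rep_c25205reverse.0 (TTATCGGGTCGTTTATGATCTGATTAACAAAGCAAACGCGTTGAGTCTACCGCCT) was at least 1029-fold higher (4.58 ± 2.37, SD, n = 3, limma adjusted p = 0.0349). The T control at 1 h differed from the other controls in both: these had levels of 4.57 to 5.75 for Rphi_rep_c28401.0 and 4.14 to 5.35 for Rphi_rep_c25205reverse.0. Both were also low on a challenged array, ECP at 1 h replicate 1 (-6.59 and -8.56). Their levels ran alike across arrays, so they may not be separate rises, and the doubt about the first may hold for both. Rphi_c16436reverse.0 (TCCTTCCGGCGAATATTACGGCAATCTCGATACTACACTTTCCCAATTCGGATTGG) was at least 11.97-fold lower (limma adjusted p = 0.00790), and its control level of -1.84 stood above those of the other controls, -7.60 to -5.15. Probe comp377983_c0_seq6.0 (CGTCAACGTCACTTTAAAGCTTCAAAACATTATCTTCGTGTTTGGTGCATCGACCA) fell by 4.30 ± 1.02 log2 (SE, adjusted p = 0.0290). Probes of the Rphi_rep_c contigs rose in 177 cases and fell in 10, and in 72 and 27 under quantile normalization.

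The T counts at 1 h depended on single arrays. They were 162, 217 and 245 without replicates 1, 2 and 3, and 1 from the arrays of this challenge alone. With close arrays averaged 0 passed in limma, where 2444 had an unadjusted p under 0.05 with each array counted, and the named probes had adjusted p-values of 0.135 to 0.200. Quantile normalization called 360, of which 55.8% were higher, against 78.4%. Normexp called 161, and the differences of the 4 named probes shrank. They were 7.84 and 7.19 log2 for the rises, which no longer passed (adjusted p = 0.0775 and 0.1004), and -2.43 and -2.85 for Rphi_c16436reverse.0 and comp377983_c0_seq6.0. For both rises and Rphi_c16436reverse.0 these lie below the bounds given. Probe comp377983_c0_seq6.0 missed the threshold under quantile normalization (adjusted p = 0.0504), and no named probe passed in the arrays of this challenge alone (0.115 to 0.157). Without replicate 2, Rphi_rep_c28401.0 (adjusted p = 0.0502), Rphi_rep_c25205reverse.0 (0.0796) and comp377983_c0_seq6.0 (0.0595) no longer passed. Without replicate 3 both rises no longer passed (0.0502 and 0.0714), and without replicate 1 the last fall did not (0.0547).

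At 8 h, trophozoites changed 4 probes. Chosen after their values were seen, comp383345_c0_seq2reverse.0 rose by 3.18 log2 (adjusted p = 0.00466), while Contig9614reverse.1 fell by 5.24 (adjusted p = 0.00891) and Contig7173reverse.1 fell by 5.01 (adjusted p = 0.000278). The count was 1 with close arrays averaged, 7 from the arrays of this challenge alone, 14 without the filter and 19 under quantile normalization, 73.7% of them higher, against 25.0%. Normexp called 6, all of them higher. The T effect differed between 8 h and 1 h in 7 probes (1 higher and 6 lower at 8 h), and in 0 with close arrays averaged. It was 12 probes without T at 8 h replicate 3.

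At 24 h, in the deposited table normalized again over complete probes, 708 of 5481 probes differed between T and its control (382 higher and 326 lower, median size 1.68 log2). The count was 175 with close arrays averaged and 1439 without replicate 3, which correlated with replicates 1 and 2 at r = 0.931 and 0.935 across probes, against 0.997 between these. It was 468 without replicate 1, 423 without replicate 2 and 223 from the arrays of this challenge alone. As deposited, the table gave 4687 calls, 97.6% of them higher, with a median difference over all probes of 1.88 log2.

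Zoospores changed 45 of 12390 probes averaged over the time points, 12 higher and 33 lower, all at least 2-fold and with a median size of 2.97 log2. Probe ruditapes2_c1595.0 (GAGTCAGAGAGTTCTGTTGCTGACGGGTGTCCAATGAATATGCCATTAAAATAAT) was at least 10.2-fold higher (adjusted p = 0.0277), and comp385481_c0_seq1reverse.0 (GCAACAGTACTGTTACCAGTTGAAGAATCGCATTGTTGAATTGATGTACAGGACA) at least 7.01-fold higher (adjusted p = 0.00752), both not well above background in the control. Probes comp378984_c0_seq1reverse.1 (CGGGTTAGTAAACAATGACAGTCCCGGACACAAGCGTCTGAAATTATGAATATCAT) and comp393194_c1_seq5.0 (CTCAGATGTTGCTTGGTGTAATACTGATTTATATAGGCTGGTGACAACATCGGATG) were at least 12.8-fold (adjusted p = 0.0180) and 10.7-fold (adjusted p = 0.00752) lower, and not well above background on any of the 7 challenged arrays. The zoospore control lay outside the range of the other controls in these probes, by less for comp385481_c0_seq1reverse.0 and comp393194_c1_seq5.0. Its level was -7.32 for ruditapes2_c1595.0, against -1.02 to 1.88 in the others, and -1.53 for comp378984_c0_seq1reverse.1, against -8.55 to -6.46. For comp385481_c0_seq1reverse.0 it was -7.71, against -6.24 to -2.10, and the T control at 1 h (-6.24) was not well above background either. For comp393194_c1_seq5.0 it was -1.78, against -7.48 to -3.68, and the ECP control at 24 h (-3.68) was well above background as well. Zoospore arrays at 8 and 24 h had mean levels of -4.69 and -3.06 for ruditapes2_c1595.0, below all controls but their own. For comp385481_c0_seq1reverse.0 the ECP controls stood at -5.96, -4.00 and -2.10 at 1, 8 and 24 h, and zoospore arrays at -4.50, -2.60 and -0.79. Its rise may therefore in part be change with time in culture, which was not tested.

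For the mean zoospore effect 2 probes passed with close arrays averaged, when none of the 4 named probes did (adjusted p = 0.124 to 0.291). Without zoospores at 8 h replicate 1 or 2 the count was 24 or 25, and ruditapes2_c1595.0 no longer passed (adjusted p = 0.0584 and 0.0563). It was 88 without zoospores at 24 h replicate 2, 302 from the arrays of this challenge alone, when ruditapes2_c1595.0 did not pass (adjusted p = 0.0815), and 3 under normexp, when no named probe passed. Under normexp the differences were 2.60 and 1.65 log2 for the named rises and -1.55 and -1.15 for the falls, all below the bounds given. Under quantile normalization 36.7% of 49 calls were higher, against 26.7%.

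By time point, zoospores changed 474 probes at 1 h (145 rose and 329 fell), 239 at 8 h (45 rose and 194 fell) and 867 at 24 h (305 rose and 562 fell), each against the same control array. The series design states that this control pools all times, while its description names 1 h alone. If it pools all times, a difference at a single time point also holds change with time in culture. So does the zoospore minus T difference, whose zoospore effect covers 1 and 8 h alone. If it holds 1 h alone, the differences at 8 and 24 h, the mean effect and the comparisons built on it hold such change. The counts were 1, 11 and 130 with close arrays averaged. The share of rises was 30.6%, 18.8% and 35.2%, and under quantile normalization 43.9%, 46.4% and 40.7%. At 24 h, where array signal was lowest, normexp called 8332 probes, 83.3% of them higher, with a median shift of 1.31 log2 over all probes. Its offset of 50 is large beside the 75th percentiles of these arrays, 112 and 184, against 626 in the control. Probes of the dim comp contigs rose in 3340 cases and fell in 130, and those of the bright Rphi_rep_c contigs in 382 and 825. These calls therefore cannot be read as a response to zoospores. The arrays of this challenge alone gave 1409, 944 and 2244 calls. At 1 h the count was 253, 260 and 245 without replicates 1, 2 and 3, and at 8 h 66 and 56 without replicates 1 and 2.

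The difference between challenges was also tested directly. The zoospore minus T difference covers 1 and 8 h, so it mixes challenge with time whichever times the zoospore control holds. The mean zoospore and ECP effects differed in 27 probes (5 higher and 22 lower with zoospores), zoospore and T effects in 13 (1 higher and 12 lower) and T and ECP effects in 1. Chosen after its value was seen, that probe, comp391990_c0_seq10reverse.0, had a T effect minus ECP effect of -4.13 log2 (adjusted p = 0.0205). Under quantile normalization 35.6% of 45 zoospore minus ECP calls were higher, against 18.5%, and 22.2% of 18 zoospore minus T calls, against 7.69%. With close arrays averaged each of these 3 counts was 0 in limma, and with each array counted 1442, 1380 and 1283 probes had an unadjusted p under 0.05. The T and ECP controls differed in 0 of 12375 probes in limma, with a smallest adjusted p of 0.141, 1146 probes at an unadjusted p under 0.05 and 1 call without the filter, and 0 with close arrays averaged. Without either control at 1 h the count was 8, and without either at 8 h 1. The mean ECP and zoospore effects shared 7 probes called in the same direction, where independent lists would share 0.534 (1 probe with close arrays averaged), and r across all probes, which are not independent, was 0.03. ECP and T shared 0, as no T probe was called, and so did T and zoospores. In the deposited table these overlaps were 11 and 5, and ranked again over complete probes 42 and 7, where T includes 24 h. The counts of these differences moved when an array was left out, and leaving out a lone control also takes its time point out of the mean. Zoospore minus ECP gave 255 calls without the ECP control at 1 h, 49 without ECP at 24 h replicate 1, 15 and 16 without zoospores at 1 h replicates 1 and 2, 10 and 12 without zoospores at 8 h replicates 1 and 2, and 43 and 62 without those at 24 h. Zoospore minus T gave 30 and 469 without the T controls at 1 and 8 h, 49 without T at 8 h replicate 2, and 0 to 5 without T at 1 h replicates 2 and 3, T at 8 h replicates 1 and 3 or any zoospore array at 1 or 8 h. T minus ECP gave 11 without either control at 1 h, 15 without ECP at 1 h replicate 3, 0 without T at 1 h replicate 2, and 2 to 5 without 9 other arrays.

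Among the 18 pairs of different challenges at different time points, ECP at 8 h and T at 1 h shared the most probes called in the same direction (147, against at most 44 in the others). These comparisons, which share no array, had 140 rises in common, where independent lists would share 18.1, and 7 falls (4.41), with 4 probes in opposite directions (21.0). For the 147 in all, chance taken within bins of probe level gives 40.5. The correlation across all probes was 0.30. The overlap was empty with close arrays averaged, as no probe was called for T at 1 h. At 24 h, T and zoospore effects had 77 probes called in opposite directions (29.6 by independent lists) and 13 in the same (28.4), with r = -0.38 across 5481 probes. These were 3 (0.845) and 6 (0.815) with close arrays averaged. The T effect here comes from the deposited table normalized again over complete probes, and the zoospore effect from scanner values. The T control column listed the fewest probes (49.3%), and the challenged zoospore arrays had the lowest signal. Opposite signs from weak arrays and from the challenges cannot be told apart here.

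Between 1 h and 24 h, 6110 probes changed in ECP arrays (2545 rose and 3565 fell), 2910 in T arrays (1291 rose and 1619 fell) and 4645 in zoospore arrays (2208 rose and 2437 fell). Median sizes were 1.63, 1.46 and 1.85 log2. In all 3 challenges 372 probes rose and 700 fell, where independent lists would share 47.3 and 91.6. Of these, 96.7% changed in the same direction between the ECP controls at 1 and 24 h, which held culture medium only. With close arrays averaged the counts were 5235, 976 and 1450, of which 113 rises and 232 falls were shared (3.49 and 9.48 by independent lists). Under normexp the counts were 3995, 1836 and 9845, with 80.8% of the zoospore calls higher, against 47.5%. The deposited table, normalized over the probes present in each column, gave shares of rises of 21.4%, 73.7% and 21.6%, against 41.7%, 44.4% and 47.5%. For ECP and T the time points lay on different slides, so slide and time cannot be told apart within these, while all zoospore arrays shared a slide.

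**Figure D3:**
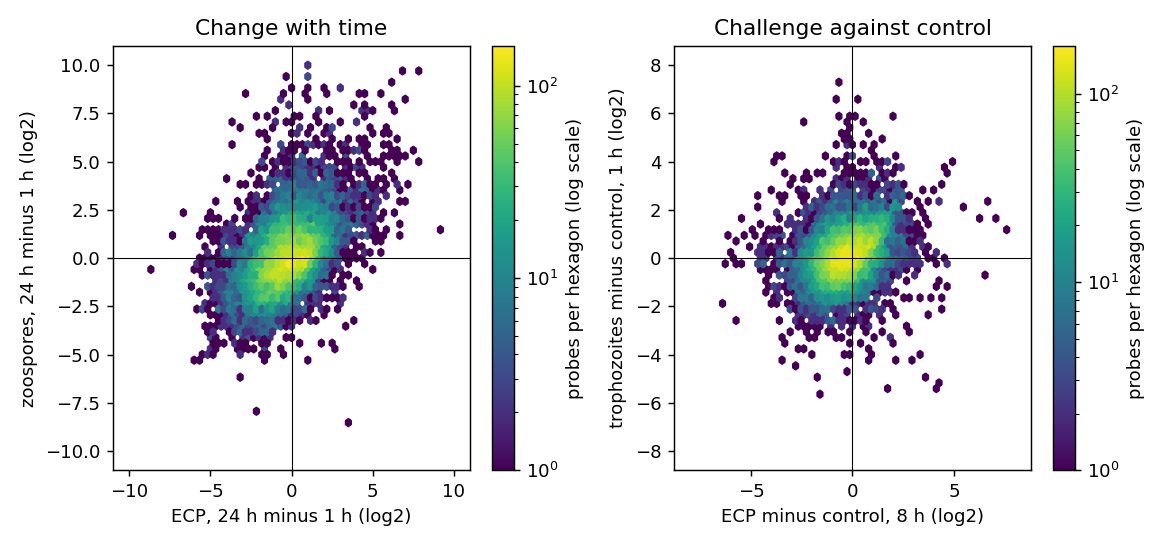
Left, change from 1 h to 24 h (log2) in ECP arrays (horizontal axis) against zoospore arrays (vertical axis); right, difference from control (log2) of ECP at 8 h (horizontal axis) against T at 1 h (vertical axis). Colour gives the probes per hexagon on a log scale; both clouds lean upwards, with r across probes of 0.48 on the left and 0.30 on the right, and 38 and 4 probes lie outside the axes.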

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

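Both tests on T at 8 h replicate 2 were chosen after the result was seen.

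The ECP effect differed between time points in 63 probes by a direct test of the change. The T effect differed between 8 h and 1 h in 7 probes. T and ECP effects differed in 1 probe, zoospore and ECP effects in 27, and zoospore and T effects in 13, each by a test of the difference itself. The difference of zoospore and T effects, over 1 and 8 h, also holds change with time in culture. For the mean ECP effect of 294 probes, 2 of the 64 choices of 1 array per time point as control gave as many, the real one included. That share is under 0.05. The ECP controls also differ from challenged arrays in being pools and in lying in slide column 1, so the share cannot separate challenge from pooling or position. The highest other choice gave 536, with ECP at 1 h replicate 2 in place of the 1 h control and the real controls at 8 and 24 h.

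The probes shared by ECP at 8 h and T at 1 h, 147 in the same direction where independent lists would share 22.5 and lists drawn within bins of probe level 40.5, were bright, with a median level of 3.16 log2 against -2.53 over all probes. With close arrays averaged T at 1 h had 0 calls in limma, so the overlap of calls was empty. An empty list does not show whether the differences themselves changed. After quantile normalization the overlap was still 7.005 times that of independent lists (84 probes). Where chance was taken within bins of probe level, it was 84 against 15.2. This argues against a shift shared by probes of similar level. It cannot exclude a response to array brightness particular to each probe, which quantile normalization leaves in place. In both comparisons the control had the lowest 75th percentile of array signal. It was 794 against 872 to 1507 for ECP at 8 h, and 327 against 668 to 1297 for T at 1 h. The slide column of the control arrays stays open as well. Over these probes, zoospore arrays at 8 h in columns 2 and 1 differed by a median of -0.07117 log2, against effects of 1.89 and 2.01. That is 1 pair of close arrays, on another slide than the ECP and T controls, so it cannot decide the question. No biological explanation was tested, and a response shared by both challenges stays open as untested. The median effect of these probes was -0.28 for T at 8 h and 0.32 for ECP at 24 h.

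T at 8 h replicate 2 correlated with replicates 1 and 3 at r = 0.959 and 0.962 across probes, against 0.981 between these, and with the ECP control at 8 h at 0.978. The T control at 8 h correlated at 0.979, 0.966 and 0.971 with replicates 1, 2 and 3, and at 0.961 with the ECP control. With the labels of replicate 2 and of the T control exchanged, the T effect at 8 h correlated with the ECP effect at 8 h at r = 0.4087, against 0.05 as given and -0.29 and -0.21 with replicate 1 or 3 as control. The exchange subtracts an array that resembles the ECP control, which the ECP effect also subtracts. That r therefore in part restates the resemblance and is weak support for an exchange. With labels as given, replicates 1 and 3 minus the control correlated with the ECP effect at 0.215, so a pool that responded little is also a candidate explanation. Replicate 2 was the replicate least like the T control, though, where a pool that responded little would be most like it. That comparison rests on a single control array. An exchange of labels and a weak response cannot be told apart here, since no sample marks either, and labels were kept as given.

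The change from 1 h to 24 h was large in every challenge. For ECP 6110 probes changed, and of the 10 splits of the 6 arrays 1, the real one, gave as many, with 1 call in the highest other; for T the same held for 1 of 10, with 2910 and 28. These splits are too few for a share under 0.05. Slide as the whole cause is argued against, as 76.01% of the probes called in ECP moved the same way in the zoospore arrays, which share a slide. Time in culture without a challenge may account for part of it. Over these probes the median change of the ECP controls was 89.12% of that of challenged arrays (1.46 against 1.63 log2), and 92.9% moved the same way, though the ECP controls at 1 and 24 h also lay on different slides. In T arrays 60.3% of these probes moved the same way, with a median of 0.26 log2 and r = 0.34 across all probes. The arrays of ECP at 24 h and of T at 1 h shared a slide. An effect of that slide would enter the ECP and T changes with opposite signs, so a part played by slide stays open. ECP and T arrays had 1426 calls in the same direction (731 by independent lists) and 374 in opposite ones (704), and 84.1% of the T calls had the same sign in zoospore arrays (r = 0.49). How much of the change is common to all challenges stays open.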

How the results depend on the processing

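The settings that average close arrays, rank the deposited table again over complete probes or leave out the zoospore arrays at 24 h were chosen after the data were seen, and the cause of a moved count was not tested unless stated. Among counts under settings other than leaving out an array, 62 stayed within 1.5 times the main count and 103 did not. Of the values of named probes under all settings, 131 kept their direction and passed, 43 kept their direction without passing, and 0 reversed. Unlike the counts before, these include fits that leave out an array. The named probes were chosen as the largest called changes in these same arrays, so the lack of reversals follows in part from that choice.

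With close arrays averaged, the counts were 13 (ECP mean), 0, 28 and 39 (ECP at 1, 8 and 24 h), 2 (zoospore mean), 1, 11 and 130 (zoospores at 1, 8 and 24 h), and 0, 1 and 175 (T at 1, 8 and 24 h). Changes from 1 h to 24 h gave 976 for T and 1450 for zoospores, changes of an effect with time 7 for ECP and 0 for T, differences between challenges 0 each and the ECP and zoospore overlap 1. This follows in part from its construction, with fewer arrays and a larger pooled spread.

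Under normexp, counts against control were 176, 2, 596 and 40 for ECP (mean, 1, 8 and 24 h), 161 for T at 1 h, and 3, 108, 35 and 8332 for zoospores. Changes from 1 h to 24 h were 3995, 1836 and 9845 for ECP, T and zoospores. Changes of an effect with time gave 2 for ECP and 0 for T, and the T minus ECP, zoospore minus ECP and zoospore minus T differences 0, 0 and 4. T and ECP controls differed in 1 probe, and the ECP and zoospore overlap was 1. The median over all probes stood at 1.31 log2 for zoospores at 24 h (-0.13 in the main setting), -0.45 for T at 1 h (0.12) and -0.35 for ECP at 24 h (-0.02). Under quantile normalization the median moved from -0.22 to -0.01 for ECP at 8 h, and the moved counts were 5 (T mean), 4 (ECP at 1 h), 19 (T at 8 h), 3 (T minus ECP) and 45 (zoospore minus ECP). Without the filter they were 11 (ECP at 1 h), 14 (T at 8 h), 2 (T minus ECP) and 1 (controls).

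The deposited table gave 89, 1, 207 and 9 for ECP, 2737, 29, 9 and 4687 for T, and 10, 149, 45 and 1337 for zoospores, each as mean, 1, 8 and 24 h. It gave 2 and 3729 for changes of the ECP and T effects with time, 1640, 2 and 1226 for the T minus ECP, zoospore minus ECP and zoospore minus T differences, 1641 for the controls and 4 for the overlap. T values there include the 24 h column with few present probes. Ranked again over complete probes, it gave 485, 1 and 51 for ECP (mean, 1 and 24 h), 384 and 13 for T (mean and 8 h) and 17, 197 and 104 for zoospores (mean, 1 and 8 h). Changes from 1 h to 24 h were 3178, 1618 and 2329, changes of the ECP and T effects 32 and 415, differences between challenges 155, 9 and 83, and controls 23. Fewer probes are tested there.

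Fits within a challenge gave 34, 0, 5 and 77 for ECP, 1, 1, 7 and 223 for T, and 302, 1409, 944 and 2244 for zoospores (mean, 1, 8 and 24 h). T changed in 1631 probes from 1 h to 24 h, and changes of the ECP and T effects gave 0 and 0. Here the spread comes from the arrays of a challenge alone. The additive model gave 0 for ECP and 1 for T. Without the zoospore arrays at 24 h, the zoospore minus ECP difference was 56, while the zoospore and ECP means, at 55 and 385, stayed within 1.5 times.

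Same-number replicates did not deviate together: 0 of 9 ECP, 0 of 9 T and 0 of 6 zoospore pairs correlated above 0.1 across probes. No pairing by number was thus seen, which does not exclude it. The zoospore pairs tell little, as arrays at 1 and 8 h were close. With 2 arrays per group at 8 and 24 h, their deviations also mirror each other. With the number as a replicate block the T mean count was 2 (random block, correlation -0.02), and T changed in 1090 probes from 1 h to 24 h (fixed block). No other count against control or with time moved by over 1.5 times under the block.

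Leaving out arrays one at a time gave these ranges, where leaving out a lone control also drops its time point. ECP mean, 28 to 778, with 778, 28 and 134 without the controls at 1, 8 and 24 h, 168 and 464 without ECP at 1 h replicates 1 and 2, 147 without ECP at 8 h replicate 1 and 463 without ECP at 24 h replicate 1. ECP at 1 h gave 2 to 7 (2 without replicate 1), at 8 h 234 to 1024 (234 and 354 without replicates 1 and 3) and at 24 h 116 to 207. T mean gave 0 to 524, with 4 and 524 without the controls at 1 and 8 h, 8 without T at 1 h replicate 1 and 96 without T at 8 h replicate 2. T at 1 h gave 162 to 245, at 8 h 4 to 5 and at 24 h 423 to 1439 (468, 423 and 1439 without replicates 1, 2 and 3). Zoospore mean gave 24 to 88, at 1 h 245 to 260, at 8 h 56 to 66 and at 24 h 902 to 1101. Changes from 1 h to 24 h gave 5388 to 5684 for ECP, 2130 to 2987 for T and 3512 to 3885 for zoospores. The change of the ECP effect gave 12 to 96 (36 and 12 without the controls at 8 and 24 h, 96 without ECP at 24 h replicate 1), and that of the T effect 7 to 12 (12 without T at 8 h replicate 3). T minus ECP gave 0 to 15 (0 without T at 1 h replicate 2, 15 without ECP at 1 h replicate 3), zoospore minus ECP 10 to 255 (10 without zoospores at 8 h replicate 1, 255 without the ECP control at 1 h) and zoospore minus T 0 to 469 (0 without T at 1 h replicate 2, 469 without the T control at 8 h). Controls gave 1 to 8 (8 without either control at 1 h, 1 without either at 8 h).

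Not run were the slide as a block, the gene lists, and for T at 24 h the settings that need its scanner file. In the scanner values each challenged group that has a control shares its slide with that control, so the block leaves those differences as they are. The slide of the T control at 24 h is not known. A lone control of a single time point cannot be left out. Signal over background was most limited in ECP at 24 h replicate 3 and the zoospore arrays at 24 h, with 60.8%, 61.5% and 64.8% of probes well above it.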

Other observations

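Contigs that carry a pair of tested probes (2915 contigs) allowed a check within arrays. The differences of both probes correlated across contigs at r = 0.62 for the mean ECP effect, 0.59 for the mean zoospore effect, 0.47 for T at 1 h and 0.81 for the change of ECP arrays from 1 h to 24 h. Of the called probes at T 1 h, 82.1% had a partner with the same sign, against 94.7% for zoospores at 1 h and 93.4% for ECP at 8 h.

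T at 24 h replicate 3 correlated across probes at r = 0.954 and 0.956 with the zoospore arrays at 24 h and at 0.947 with the ECP control at 24 h, above its correlations of 0.931 and 0.935 with replicates 1 and 2 of its own group. Its 75th percentile of signal was 300, with 184 and 112 in those zoospore arrays and 389 in that control, against 609 and 756 in replicates 1 and 2. Shared low signal and a likeness of the samples cannot be told apart here. The 147 probes shared by ECP at 8 h and T at 1 h had the same sign in 85.0% of cases for ECP at 24 h and 70.7% for zoospores at 24 h, but in 22.4% for T at 8 h and 26.5% for zoospores at 1 h.

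Probes Rphi_rep_c28401.0 and Rphi_rep_c25205reverse.0, the largest rises with T at 1 h, varied widely elsewhere. In zoospore arrays their levels were -3.92 and -4.00 log2 at 1 h, 5.20 and 4.88 at 8 h, and 7.42 and 7.06 at 24 h, with 5.63 and 5.32 in the zoospore control. In ECP arrays at 1 h the SD of 3 replicates was 6.20 and 7.10 log2, as replicate 1 stood at -6.59 and -8.56. The levels of both probes thus moved together, and whether they report a single signal was not tested.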
